A study of Mus musculus with 16 samples.

How the data were processed

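Gene expression was measured on 2-colour arrays in Ba/F3 cells, a mouse pro-B cell line that depends on interleukin-3. The cells were clonal lines that stably expressed FOXO3(A3)-ER or FOXO4(A3)-ER, fusions of a forkhead transcription factor with an oestrogen receptor domain, and were given 4-hydroxytamoxifen (4-OHT), which switches such fusions on. Each of the 16 arrays held RNA of 1 treated culture in 1 dye and RNA of the same line's pool of time 0 cells in the other. Per the labels, the arrays formed 4 groups of 4 (FOXO3 at 2 h, FOXO3 at 8 h, FOXO4 at 2 h and FOXO4 at 8 h), and in each group 2 arrays carried the treated RNA in Cy5 and 2 in Cy3. The series design calls the replicates of a time point independent.

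Per the labels' protocols, RNA was amplified from a T7 primer into aminoallyl-labelled cRNA, with external control RNA added before amplification, and coupled to the dyes. Per the file headers, the scanner files give the mean intensity of each spot in 2 channels with the median and SD of its local background, not subtracted. The authors also deposited normalized Cy5 and Cy3 intensities of each array and a table of log2 values. The log2 values equalled log2(treated / time 0) of those normalized intensities to within 5e-06, which settled their scale and direction, and their column medians lay between -0.0124 and 0.011. The method of that normalization, the scanner and the image software are not given in the sources used here. Channel 1 of the scanner files was taken as Cy5, since over the spots of an array it correlated more closely with the deposited Cy5 values than with the Cy3 values on 16 of 16 arrays.

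The scanner intensities were the starting point. Background was corrected with normexp (offset 50), ratios were normalized within each array by loess with control spots at weight 0, and no scaling was applied between arrays. Each ratio was turned to treated over time 0. Each array had 34992 spots, of which 3223 were controls and 31769 were gene probes. Probes were kept when they exceeded the local background by 2 background SDs in either channel on at least 4 arrays, which left out 942 gene probes. The platform annotation gave 1 symbol for 26000 gene probes, several for 0 and none for 5769. Of its 17888 symbols, 15860 were current in the RefSeq table of GRCm38.p6, 1981 were updated through a synonym and 47 were kept as given. The brightest probe stood for a gene, and 4662 of the 17484 genes tested had over 1 probe. No coordinates are given, because the array's build is not given in the sources used here.

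The median spot signal per array was 94.8 to 169 in Cy5 and 98.2 to 161 in Cy3, over a median background of 38 to 42 and 40 to 45. Between 96.5% and 97.2% of gene probes lay above the local background, and 30.4% to 42.4% lay above the 95th percentile of the external control spots, leaving out the 144 spots of the 1 of 14 control types that gave a detectable signal. A gene below that percentile is called dim in the text. Between 0 and 12 spots per array were saturated. The number of arrays limits the precision: the median SE was 0.0501 for a group's log2 ratio and 0.0709 for a difference between groups. Pairs of arrays of 1 group differed on nearly every spot, and none was a copy of another.

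All 16 arrays entered 1 limma fit (lmFit and eBayes) with 4 group means and a gene-specific dye term. The SD of the dye term over genes was 0.212 on the log2 scale. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene is from this fit. The time 0 pool was 1 control sample per line, so the ratios against 0 h leave out the spread of time 0 cultures. The 8 comparisons were each group against its pool, 8 h against 2 h within each line, and FOXO3 against FOXO4 at each time. The 26 gene lists, which included 3 lists of cell-type markers, were tested with camera at a preset correlation of 0.01, adjusted over the lists, and also with an estimated correlation and with fry, whose directional p does not set a list against other genes. Some genes stood in over 1 list, among them Eprs, Id1, Myc and Sesn1, so shifts of different lists are not independent. The groups, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined.

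The rule named, for each comparison against 0 h, the 10 genes of highest and the 10 of lowest log2 ratio among called genes with the same sign on all 4 arrays, and 5 and 5 for the other comparisons, leaving out clone and predicted-gene names. It added up to 4 members of smallest adjusted p from each list discussed and a set of glutamine, FOXO, cell cycle and autophagy genes whether called or not. Not all of that set is analysed here.

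The fit was checked on simulated data for the FOXO3 comparison of 8 h against 0 h over 17484 genes: it recovered 47 of 50 genes changed by a log2 ratio of 0.3 and 50 of 50 at each of 0.6, 1 and 2, and it called 11 of 17284 unchanged genes. In simulated data for the FOXO4 comparison of 8 h against 0 h the list test called 1 of 26 lists, the one that was shifted. Genes were drawn independently there, so the check does not cover lists whose members are correlated. The simulated time 0 pool carried no error either, so the 11 calls leave out false calls that an error of the pool would bring. R 4.3.3, limma 3.58.1, statmod 1.5.0 and data.table (version 1.17.8) were used. The alternatives were the background correction, the normalization within and between arrays, centring on the spots of the detectable external control, the filter on dim probes, the mean of a gene's probes or every probe alone, no dye term, a replicate block, a fit for each line, another variance prior, the authors' values, other set tests, and leaving out each array in turn. A filter at the control spots, a dye term for each line and the overlaps between lines and times were chosen after seeing the data.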

Results

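The arrays followed the transcripts of Ba/F3 cells after FOXO3 or FOXO4 was switched on with 4-OHT. The series title places them in a study of glutamine metabolism and autophagy under the PI3K, PKB and FOXO pathway. There were 4 arrays for each line and time, and 17484 genes were tested. No array held cells without a fusion protein, or cells kept for 2 h or 8 h without 4-OHT. Values are log2 ratios of treated cells over the line's time 0 pool, with the SE of the limma fit (n = 4 arrays per group), and adjusted p-values are Benjamini-Hochberg values from limma for genes and from camera for lists. The 10 highest and 10 lowest genes named for a comparison against 0 h had the same sign on 4 of 4 arrays. Every gene named was above its local background on the arrays of its group, and dim probes among these ranked genes are pointed out. At time 0 Bcl2l11, Bcl6, Btg1, Ccnd1, Cdkn1b, Gadd45a, Foxo1, Foxo3, Foxo4 and Ulk1 were dim on at least 3 of 4 arrays of each group, so their ratios have a low starting signal.

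In FOXO3 cells at 2 h Clk1, a kinase of SR splicing factors, rose by 1.56 ± 0.071, a fold change of 2.95, and Cited2, a transcriptional co-regulator and known FOXO target, rose by 1.47 ± 0.092. Noct, which encodes nocturnin, rose by 1.46 ± 0.069. The genes that fell most were Banp, at -1.42 ± 0.058, and Id1, an inhibitor of helix-loop-helix factors, at -1.31 ± 0.055. Myc, the growth-promoting transcription factor, fell by 0.71 ± 0.047, and the stress gene Gadd45a rose by 0.58 ± 0.099, a call lost without the dye term (adjusted p = 0.0859). In all, 1364 genes were called, 606 higher and 758 lower. Of these, 13 rose and 5 fell by at least 1 on the log2 scale.

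The other genes of largest rise in FOXO3 cells at 2 h were Fbxo30 (1.32), Resf1 (1.30), Klf6, a zinc-finger factor (1.28), Rnf19b (1.21), Zranb1 (1.20), the cold-inducible RNA-binding gene Cirbp (1.13) and the caveolin gene Cav2 (1.09). The largest adjusted p among the 10 genes of highest ratio was 4.04e-08. The other genes of largest fall were Nfe2 (-1.30), Mycn (-1.18), Gfi1b (-1.16), Ets2 (-0.90), Myb (-0.88), Ier3 (-0.84), the hexokinase gene Hk2 (-0.84) and Rgcc (-0.83). The largest adjusted p among the 10 of lowest ratio was 1.68e-08. A dimmer probe of Noct gave -0.39, and 1 of 2 other probes of Myb gave 0.02. At time 0 Klf6 was dim on 4 of 4 arrays, and Ets2 and Gfi1b were dim in treated cells on 2 of 4.

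Among 44 genes known to be induced by FOXO factors, 9 rose, 2 fell and 33 were not called in FOXO3 cells at 2 h (10 rose and 3 fell adjusted over the list alone), and the list shifted up (adjusted p = 0.000301). Its members of smallest adjusted p were Cited2, Klf6, Sesn1, a stress-induced inhibitor of mTORC1 (0.96 ± 0.069), and the antiproliferative gene Btg1 (0.70 ± 0.061). Of 7 genes known to be repressed by FOXO factors, 0 rose, 3 fell and 4 were not called (0 and 3 adjusted over the list alone; adjusted p = 2.1e-05). The 3 were Id1, Myc and the kinase gene Pim1 (-0.60 ± 0.071). Of 36 genes of the response to interleukin-3 and STAT5, 0 rose, 12 fell and 24 were not called (1 and 13 adjusted over the list alone; adjusted p = 2.51e-06). Leading members were Id1, Ier3, Myc and Cish (-0.48 ± 0.054). Of 28 genes of the unfolded protein response and heat shock, 0 rose, 9 fell and 19 were not called (1 and 10 adjusted over the list alone; adjusted p = 6.25e-06). Those lower included the chaperone genes Hsph1 (-0.67 ± 0.051) and Dnajb1 (-0.71 ± 0.056), Herpud1 (-0.63 ± 0.04) and Xbp1 (-0.29 ± 0.057).

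Of 34 aminoacyl-tRNA synthetase genes and ATF4 targets, 0 rose, 8 fell and 26 were not called in FOXO3 cells at 2 h (0 and 11 adjusted over the list alone; adjusted p = 0.000124). Atf4 itself stood at -0.32 ± 0.045, with Mthfd2 at -0.26, Iars at -0.24 and Trib3 at -0.35. Antioxidant genes shifted up, 8 rising, 0 falling and 19 not called of 27 (11 and 2 adjusted over the list alone; adjusted p = 0.00106). Txnip, a member of that list but not itself an antioxidant enzyme gene, stood at 0.34 ± 0.042. Cat, the catalase gene, stood at 0.25 and Txnrd1 at 0.25. Of 43 autophagy genes, 4 rose, 0 fell and 39 were not called (4 and 0 adjusted over the list alone; adjusted p = 0.0058): Wdr45 (0.23), Rb1cc1 (0.27), the receptor gene Sqstm1 (0.28) and Atg14 (0.23). The calls of the antioxidant and autophagy lists were lost with median centring in place of loess (adjusted p = 0.06 for each).

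Of 46 ribosome biogenesis genes, 1 rose, 9 fell and 36 were not called in FOXO3 cells at 2 h (1 and 13 adjusted over the list alone), and the list shifted down (adjusted p = 0.00174, but adjusted p = 0.0621 with an estimated correlation). Wdr12 stood at -0.24, Polr1b at -0.27 and Polr1c at -0.21, and Dkc1 rose by 0.25. Of 24 glycolysis genes, 0 rose, 4 fell and 20 were not called (0 and 5 adjusted over the list alone; adjusted p = 0.00364, but adjusted p = 0.152 with an estimated correlation). The 4 were Hk2, the glucose transporter genes Slc2a1 (-0.46) and Slc2a3 (-0.38), and Pfkp (-0.18). Without FOXO3 replicate 3 at 2 h the list's adjusted p was 0.148. Of 25 genes of cholesterol and fatty acid synthesis, 2 rose, 6 fell and 17 were not called (3 and 7 adjusted over the list alone; adjusted p = 0.0291, but adjusted p = 0.0538 with an estimated correlation), led by Scd2 (-0.34), Sqle (-0.35), Msmo1 (-0.41) and Mvd (-0.20). Its adjusted p was 0.0628 without replicate 1 and 0.105 without replicate 3 of this group, and 0.0715 with a filter at the control spots. The other 16 lists were not shifted, among them glutamine and glutamate metabolism (adjusted p = 0.569) and the 3 marker lists, of B-lineage cells (adjusted p = 0.209), mast cells, basophils and myeloid cells (adjusted p = 0.23) and T, NK and erythroid cells (adjusted p = 0.321). In 8 of these 16 the median, mean and test differed in sign, with medians between -0.03 and 0.014.

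Glul, which encodes glutamine synthetase, was at 0.20 ± 0.05 in FOXO3 cells at 2 h (adjusted p = 0.016; higher on 4 of 4 arrays). The Glul call was lost under centring on the external control spots (adjusted p = 0.58), with the mean of its probes (0.504), with median centring (0.107), without the dye term (0.104), and without replicate 3 (0.132) or 4 (0.14) of the group. The death gene Bcl2l11 (0.13 ± 0.062), the cell cycle inhibitor gene Cdkn1b (0.14 ± 0.057), Gabarapl1 (0.13 ± 0.043), Map1lc3b (0.07 ± 0.053), Bnip3 (-0.06 ± 0.086), Ulk1 (-0.08 ± 0.05), Asns (-0.03 ± 0.054), the glutamine transporter gene Slc1a5 (-0.07 ± 0.057), Bcl6 (0.01), Irs2 (-0.02), Ccnd1 (-0.01), Ccnd2 (-0.01), Foxo1 (0.03), Foxo3 (0.04) and Foxo4 (-0.02) were not called at 2 h. All comparisons against 0 h rest on 1 pool per line. In a simulation of unchanged groups the pool deviated as 1 array does. Over 10 draws, an average of 3968 genes were called in the place of FOXO3 at 2 h and 3930 in that of 8 h. Such a pool error is larger than these data allow, since 1364 genes were called for FOXO3 at 2 h. The difference between the lines at 2 h holds the errors of both pools, and 6 genes were called there. Without the dye term 466 genes were called for FOXO3 at 2 h, and 529 with centring on the external control spots.

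At 8 h in FOXO3 cells the response was broader. Noct rose by 3.60 ± 0.069, a fold change of 12.1, and Lancl3 and the tetraspanin gene Tspan8 by 3.05 ± 0.089 and 3.03 ± 0.053. Gzmb, which encodes granzyme B, fell by 2.34 ± 0.063, a fold change of 5.06, and the tubulin gene Tuba8 fell by 1.87 ± 0.077. Glul rose by 1.24 ± 0.05, a fold change of 2.36 (adjusted p = 4.78e-13; higher on 4 of 4 arrays), and the autophagosome gene Map1lc3b by 1.65 ± 0.053. In all, 5329 genes were called, 2688 higher and 2641 lower, of which 241 rose and 31 fell by at least 1 on the log2 scale. Centring on the external control spots gave 1534 higher and 2552 lower, median centring gave 2249 and 2653, and 3392 genes were called without the dye term.

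The other genes of highest ratio in FOXO3 cells at 8 h were Trp53inp1, a p53-induced stress gene (2.82), the nucleotide receptor gene P2ry14 (2.80), the galectin gene Lgals3 (2.72), the ubiquitin-conjugating enzyme gene Ube2h (2.67), Cav2 (2.67), Resf1 (2.55) and Ccpg1 (2.45), with an adjusted p of at most 4.15e-14 among the 10. The other genes of lowest ratio were Col5a1 (-1.65), Baiap2 (-1.48), the corepressor gene Cbfa2t3 (-1.46), Ppid (-1.30), Tuba4a (-1.30), the survival gene Bcl2 (-1.22), Cdca7 (-1.21) and Cmtm7 (-1.21), with an adjusted p of at most 8.6e-11 among the 10. At time 0 the probes of Lancl3, Trp53inp1, P2ry14, Lgals3, Ube2h and Ccpg1 were dim on at least 1 array, as were those of Col5a1 and Bcl2 in treated cells. The dimmer probe gave -0.41 for Noct, 0.04 for Ccpg1 and -0.06 for Baiap2, and 2 of 6 other probes of Col5a1 were called lower.

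Of the 43 autophagy genes, 30 rose, 1 fell and 12 were not called in FOXO3 cells at 8 h (31 and 1 adjusted over the list alone; adjusted p = 1.97e-11). Beside Map1lc3b they included Sqstm1 (1.88 ± 0.062), Wdr45 (1.13 ± 0.041), Gabarapl2 (1.14 ± 0.044), Gabarapl1 (0.71 ± 0.043), the mitophagy gene Bnip3 (0.26 ± 0.086, adjusted p = 0.0273) and the initiating kinase gene Ulk1 (0.46 ± 0.05). Ulk1 was not called without the dye term (adjusted p = 0.415). Bnip3 lost its call under centring on the external control spots (adjusted p = 0.22), in a fit of the line alone (0.0544), with median centring (0.143), without the dye term (0.256) and without replicate 1 (0.161), 2 (0.0583) or 4 (0.0967) of the group. Of 41 lysosome genes, 19 rose, 7 fell and 15 were not called (19 and 7 adjusted over the list alone; adjusted p = 0.00424, but adjusted p = 0.097 with an estimated correlation). The proton pump genes Atp6v1d (1.37) and Atp6v1e1 (0.90) and Lamp2 (1.21) were higher and Gusb (-0.77) was lower.

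Of the FOXO-induced genes 21 of 44 rose, 2 fell and 21 were not called in FOXO3 cells at 8 h (21 and 2 adjusted over the list alone; adjusted p = 1.8e-08). Leading members were Btg1 (1.87 ± 0.061), Sesn1 (1.80 ± 0.069), Cited2 (2.38 ± 0.092) and Pik3ip1, an inhibitor of PI3K (1.37 ± 0.053). Gadd45a rose by 1.95 ± 0.099, Bcl2l11 by 0.91 ± 0.062 and Cdkn1b by 0.51 ± 0.057, and a dimmer probe of Bcl2l11 by 0.53. Of the 7 FOXO-repressed genes 0 rose, 3 fell and 4 were not called (0 and 3 adjusted over the list alone; adjusted p = 0.0158, but adjusted p = 0.157 with an estimated correlation and 0.0777 with the filter at the control spots): Id1 (-0.74), the cyclin gene Ccnd2 (-0.67) and Cdk4 (-0.36). Myc was at -0.10 ± 0.047 and was not called. Of 28 genes of the BCL2 family and apoptosis, 12 rose, 3 fell and 13 were not called (12 and 4 adjusted over the list alone; adjusted p = 0.0464, but adjusted p = 0.097 with an estimated correlation). Bcl2 and Bid (-0.65) were lower and Bcl2l11 and Casp6 (0.73) higher. That last list shift was lost under 5 other settings, with adjusted p-values of 0.0527 to 0.0997, and without replicate 3 (0.0651) or 4 (0.0698) of the group or without FOXO4 replicate 2 at 2 h (0.0521).

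Of 46 ribosome biogenesis genes, 1 rose, 41 fell and 4 were not called in FOXO3 cells at 8 h (1 and 42 adjusted over the list alone; adjusted p = 2.89e-24), led by Nop58 (-1.01), Ddx21 (-0.91), Nop56 (-0.84) and Wdr12 (-0.71). The list of cytosolic ribosomal proteins was not shifted (adjusted p = 0.604). Of 42 genes of DNA replication and S phase, 1 rose, 36 fell and 5 were not called (1 and 37 adjusted over the list alone; adjusted p = 4.47e-20). Leading members were the licensing gene Cdt1 (-0.97), Rrm2 (-1.03), Uhrf1 (-0.96) and Tk1 (-1.05). Of 42 genes of mitosis and G2/M, 10 rose, 21 fell and 11 were not called (10 and 22 adjusted over the list alone; adjusted p = 0.0276, but adjusted p = 0.125 with an estimated correlation). Ndc80 (0.85), Nusap1 (0.86) and Ccnb2 (0.65) were higher and Ccna2 (-0.47) was lower. The mitosis call was also lost with centring on the external control spots (adjusted p = 0.142), without the dye term (0.0513) and with the filter at the control spots (0.15). Of 34 synthetase genes and ATF4 targets, 1 rose, 21 fell and 12 were not called (2 and 22 adjusted over the list alone; adjusted p = 6.12e-08), led by Eprs (-0.63), Iars (-0.54), Tars (-0.50) and Yars (-0.65). Asns, which encodes asparagine synthetase, fell by 0.47 ± 0.054.

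The list of glutamine and glutamate metabolism shifted down in FOXO3 cells at 8 h, with 6 genes rising, 15 falling and 9 not called of 30 (6 and 16 adjusted over the list alone; adjusted p = 0.00869, but adjusted p = 0.0952 with an estimated correlation). Glul and the CTP synthase gene Ctps2 (0.91 ± 0.047) rose, and Eprs and the proline dehydrogenase gene Prodh (-0.56 ± 0.034) fell. Eprs was also a member of the list of synthetases and ATF4 targets. A dimmer probe of Glul rose by 0.30. Of 22 amino acid transporter genes, 3 rose, 7 fell and 12 were not called (3 and 8 adjusted over the list alone), and the list was not shifted (adjusted p = 0.146), although Slc1a5 fell by 0.62 ± 0.057. Of 24 glycolysis genes, 2 rose, 8 fell and 14 were not called (2 and 9 adjusted over the list alone; adjusted p = 0.00698, but adjusted p = 0.157 with an estimated correlation). Leading members were Hk2 (-0.96), Pdk1 (-0.69), Pgam1 (-0.47) and Hk1 (-0.51). Of 25 genes of cholesterol and fatty acid synthesis, 1 rose, 14 fell and 10 were not called (1 and 14 adjusted over the list alone; adjusted p = 0.00028). Scd2 (-0.93), Acaca (-0.71) and Idi1 (-0.53) were lower and Cyp51 (0.64) was higher. The 3 marker lists were not shifted, with adjusted p-values of 0.559 for B-lineage, 0.279 for mast cell, basophil and myeloid and 0.642 for T, NK and erythroid markers. In 2 of the 14 lists not shifted the median, mean and test differed in sign.

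The Foxo3 transcript itself rose by 0.69 ± 0.045 in FOXO3 cells at 8 h and Foxo4 by 0.16 ± 0.043, whereas Foxo1 (-0.02), Bcl6 (0.00), Irs2 (0.06) and Ccnd1 (-0.01) were not called. The Foxo4 call was lost under centring on the external control spots (adjusted p = 0.43), with median centring (0.0595), without the dye term (0.221) and without replicate 2 of the group (0.0538). Whether the Foxo3 probe also reads the transgene is not known here. The mean log2 signal of Foxo3 was 7.43 in the FOXO3 line and 6.53 in the FOXO4 line, and that of Foxo4 was 6.90 and 7.31.

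**Figure D1:**
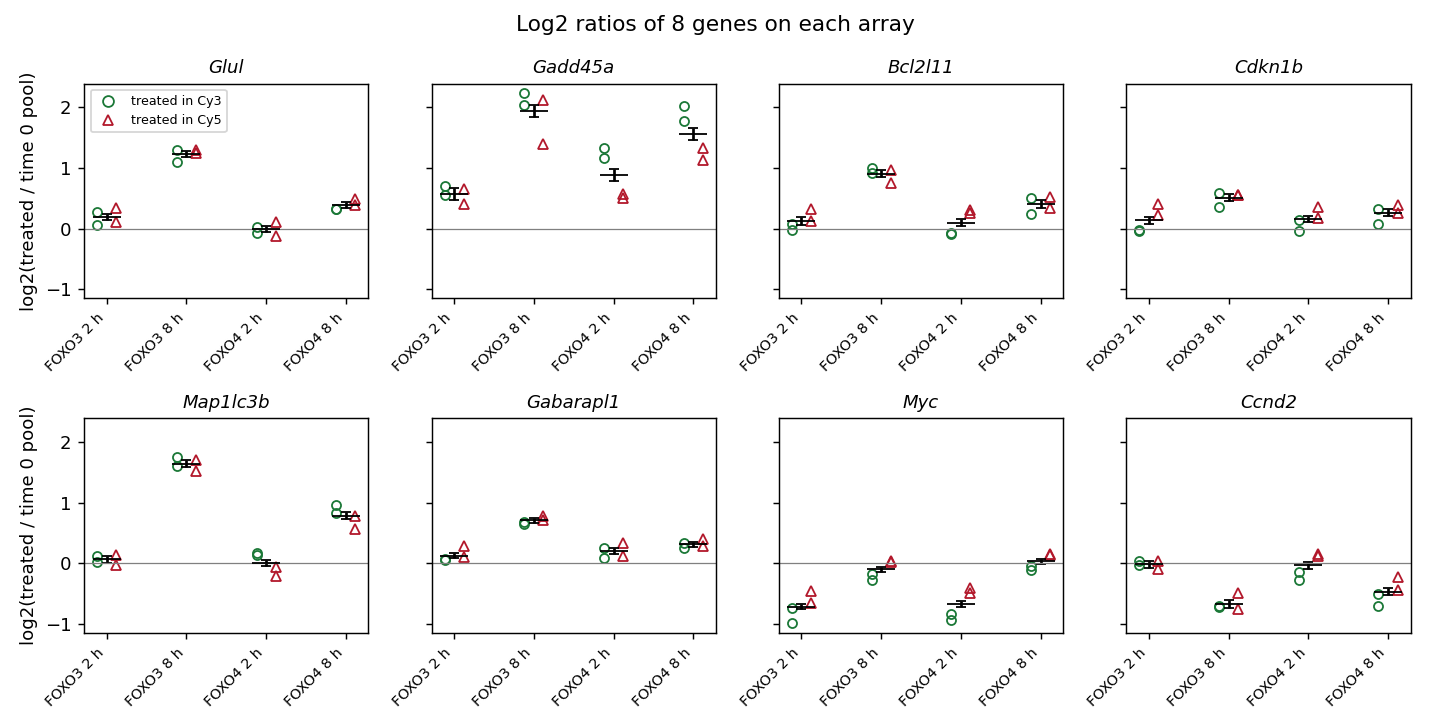
Log2 ratios of treated cells over the time 0 pool (y axis) for 8 genes in the 4 groups (x axis). Points are single arrays before the dye term is removed, circles with the treated RNA in Cy3 and triangles in Cy5, and bars are group means ± SE of the limma fit (n = 4). Glul stood at 1.24 in FOXO3 cells at 8 h and at 0.39 in FOXO4 cells.

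In FOXO4 cells at 2 h several of the genes named for FOXO3 led as well. Fbxo30 rose by 1.49 ± 0.063, a fold change of 2.82, Cited2 by 1.44 ± 0.092 and Klf6 by 1.43 ± 0.084. Banp fell by 1.71 ± 0.058, a fold change of 3.26. Id1 stood at -1.59 ± 0.055 and the blood cell factor gene Gfi1b at -1.52 ± 0.04. Myc fell by 0.67 ± 0.047 and Gadd45a rose by 0.89 ± 0.099. In all, 1538 genes were called, 592 higher and 946 lower, and 10 rose and 10 fell by at least 1 on the log2 scale. The count was 1015 without FOXO4 replicate 1 at 2 h, 480 without the dye term and 1009 with median centring. Centring on the external control spots moved the median of all genes by -0.11 in this group, the largest such shift, and gave 110 higher and 1094 lower, so that directions here are relative to the average gene.

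The remaining genes of highest ratio in FOXO4 cells at 2 h were Noct (1.43), Rnf19b (1.39), Ccm2 (1.23), Clk1 (1.21), Cirbp (1.07), P2ry14 (1.01) and Resf1 (1.00), with an adjusted p of at most 1.09e-08 among the 10. Those of lowest ratio were Nfe2 (-1.50), Mycn (-1.46), Myb (-1.36), Ier3 (-1.12), the haematopoietic factor genes Gata2 (-1.06), Cbfa2t3 (-1.05) and Klf1 (-1.02), with an adjusted p of at most 1.13e-09 among the 10. At time 0 Klf6, Fbxo30, Cirbp and P2ry14 were dim on at least 1 array, and Klf1 was dim in treated cells on 4 of 4. A dimmer probe of Noct gave -0.29, and 1 of 2 other probes of Myb gave -0.05.

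Of the 44 FOXO-induced genes, 8 rose, 2 fell and 34 were not called in FOXO4 cells at 2 h (12 and 2 adjusted over the list alone; adjusted p = 0.017). The median of that list was -0.004 although its mean was 0.109 and its test upward. Klf6, Cited2 and Sesn1 (0.84 ± 0.069) rose, and Cdkn1a, the p21 gene, fell by 0.79 ± 0.053. Of the 7 FOXO-repressed genes, 0 rose, 3 fell and 4 were not called (0 and 4 adjusted over the list alone; adjusted p = 5.3e-06), and Id1, Myc and Pim1 (-0.94) were lower. Of 36 genes of the interleukin-3 and STAT5 response, 2 rose, 11 fell and 23 were not called (3 and 14 adjusted over the list alone; adjusted p = 5.3e-06). Id1, Ier3, Myc and Cish (-0.75 ± 0.054) were among those lower. Of 28 genes of the unfolded protein response and heat shock, 1 rose, 10 fell and 17 were not called (1 and 17 adjusted over the list alone; adjusted p = 4.98e-06). Leading members were Dnajb1 (-0.76), Hsph1 (-0.58), Herpud1 (-0.29) and the chaperone gene Hspa5 (-0.42). Of 27 antioxidant genes, 3 rose, 0 fell and 24 were not called (6 and 0 adjusted over the list alone; adjusted p = 0.000955): Sesn1, Gsr (0.23) and Cat (0.23).

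The other 21 lists were not shifted in FOXO4 cells at 2 h, among them autophagy (3 rose, 1 fell and 39 were not called, 4 and 2 adjusted over the list alone, adjusted p = 0.151), glutamine and glutamate metabolism (2 rose, 1 fell and 27 were not called, 2 and 1 adjusted over the list alone, adjusted p = 0.431) and the 3 marker lists (B-lineage, adjusted p = 0.881, mast cell, basophil and myeloid, adjusted p = 0.703, and T, NK and erythroid, adjusted p = 0.151). In 3 of the 21 the median, mean and test differed in sign. Gabarapl1 rose by 0.21 ± 0.043 (adjusted p = 0.00418), a call lost with centring on the external control spots (adjusted p = 0.402) and with median centring (0.078). Glul (-0.01 ± 0.05), Map1lc3b (0.01 ± 0.053), Bcl2l11 (0.10 ± 0.062), Cdkn1b (0.16 ± 0.057), Asns (0.03), Slc1a5 (-0.04), Bnip3 (0.06), Ulk1 (0.05), Bcl6 (0.00), Irs2 (-0.03), Ccnd1 (-0.02), Ccnd2 (-0.03), Foxo1 (-0.02), Foxo3 (0.01) and Foxo4 (-0.07) were not called. The dimmer probe of Ccnd2, however, gave -0.34 and was called.

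At 8 h in FOXO4 cells Noct rose by 2.87 ± 0.069, a fold change of 7.31, P2ry14 by 2.17 ± 0.069 and Lancl3 by 2.16 ± 0.089. Gzmb fell by 2.12 ± 0.063, a fold change of 4.35, and Tuba8 stood at -1.68 ± 0.077. Glul rose by 0.39 ± 0.05, a fold change of 1.30 (adjusted p = 1.1e-05; higher on 4 of 4 arrays), and Map1lc3b by 0.79 ± 0.053. In all, 3227 genes were called, 1697 higher and 1530 lower, of which 75 rose and 9 fell by at least 1 on the log2 scale. The count was 1608 without the dye term and 1856 (823 higher and 1033 lower) with centring on the external control spots, and median centring gave 1663 higher and 968 lower.

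The remaining genes of highest ratio in FOXO4 cells at 8 h were Tspan8 (2.13), Cited2 (1.91), Neurl3 (1.91), Klf6 (1.84), the kinase gene Prkx (1.82), Ube2h (1.69) and Trp53inp1 (1.68), with an adjusted p of at most 1.96e-10 among the 10. Those of lowest ratio were Col5a1 (-1.47), Baiap2 (-1.41), Cbfa2t3 (-1.40), the cyclooxygenase gene Ptgs1 (-1.25), the adaptor gene Sla2 (-1.15), Endod1 (-1.05), Bcl2 and Dok2, with an adjusted p of at most 6.79e-11 among the 10. At time 0 P2ry14, Lancl3, Neurl3, Klf6, Prkx, Ube2h and Trp53inp1 were dim on at least 1 array. The dimmer probe gave 0.04 for Glul and 0.12 for Bcl2l11, neither called, and -0.10 for Baiap2 and -0.29 for Noct.

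Of the 43 autophagy genes, 22 rose, 1 fell and 20 were not called in FOXO4 cells at 8 h (24 and 1 adjusted over the list alone; adjusted p = 2.85e-08). Leading members were Map1lc3b, Sqstm1 (0.90 ± 0.062), Gabarapl2 (0.52 ± 0.044) and Bnip3 (0.76 ± 0.086). Gabarapl1 rose by 0.32 and Ulk1 by 0.25, the latter not called without the dye term (adjusted p = 1) or with centring on the external control spots (0.0777). Of 41 lysosome genes, 12 rose, 3 fell and 26 were not called (16 and 4 adjusted over the list alone; adjusted p = 0.00169, but adjusted p = 0.0947 with an estimated correlation). Leading members were Atp6v1d (0.72), Atp6v1e1 (0.39), Scarb2 (0.42) and the cathepsin gene Ctsc (0.55). Of the 44 FOXO-induced genes, 16 rose, 0 fell and 28 were not called (16 and 1 adjusted over the list alone; adjusted p = 4.53e-07). Leading members were Klf6, Cited2, Sesn1 (1.29) and Gadd45a (1.56 ± 0.099). Bcl2l11 rose by 0.41 ± 0.062 and Cdkn1b by 0.26 ± 0.057, the latter not called without the dye term (adjusted p = 0.0553) or with centring on the external control spots (0.0557). Of the 7 FOXO-repressed genes, 0 rose, 4 fell and 3 were not called (0 and 4 adjusted over the list alone; adjusted p = 0.00628, but adjusted p = 0.104 with an estimated correlation): Id1 (-0.67), Ccnd2 (-0.47), Bcl2l1 (-0.16) and Pim1 (-0.24).

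Of 42 genes of DNA replication and S phase, 1 rose, 29 fell and 12 were not called in FOXO4 cells at 8 h (1 and 35 adjusted over the list alone; adjusted p = 1.02e-16). Leading members were Tk1 (-0.67), Uhrf1 (-0.54), Cdt1 (-0.46) and Pold1 (-0.67). Of 46 ribosome biogenesis genes, 1 rose, 26 fell and 19 were not called (1 and 31 adjusted over the list alone; adjusted p = 3.67e-13). Leading members were Wdr12 (-0.48), Nop56 (-0.50), Ddx21 (-0.52) and Tcof1 (-0.61). Of 34 synthetase genes and ATF4 targets, 0 rose, 8 fell and 26 were not called (0 and 8 adjusted over the list alone; adjusted p = 0.00147, but adjusted p = 0.0702 with an estimated correlation and 0.0753 with median centring). Leading members were Tars (-0.37), Eprs (-0.30), Iars (-0.29) and Yars (-0.37). Of 27 antioxidant genes, 7 rose, 2 fell and 18 were not called (8 and 3 adjusted over the list alone; adjusted p = 0.0493, but adjusted p = 0.096 with an estimated correlation). Sesn1, Glrx (0.97), the mitochondrial superoxide dismutase gene Sod2 (0.67) and Cat (0.55) were higher. Of 28 genes of the unfolded protein response and heat shock, 9 rose, 3 fell and 16 were not called (11 and 4 adjusted over the list alone; adjusted p = 0.0336, but adjusted p = 0.104 with an estimated correlation). Xbp1 (0.89), Pdia4 (0.42) and Dnajb9 (0.47) were higher and Hsp90aa1 (-0.28) was lower. These last shifts lay at the threshold: leaving out FOXO4 replicate 3 at 8 h ended that of the unfolded protein response (adjusted p = 0.065). It also ended with the filter at the control spots (0.229), print-tip loess (0.0638) and the authors' values (0.0759), and that of the antioxidant list ended under 7 other settings, with adjusted p-values of 0.0502 to 0.116. Leaving out any of 11 single arrays ended that of the antioxidant list (adjusted p between 0.0504 and 0.0641).

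The list of glutamine and glutamate metabolism was not shifted in FOXO4 cells at 8 h, with 4 genes rising, 11 falling and 15 not called of 30 (4 and 13 adjusted over the list alone; adjusted p = 0.17). Glycolysis (adjusted p = 0.358), cholesterol and fatty acid synthesis (0.571), mitosis and G2/M (0.836), the BCL2 family (0.659) and the marker lists of B-lineage cells (0.659), mast cells, basophils and myeloid cells (0.0781) and T, NK and erythroid cells (0.781) were not shifted either. In 7 of the 17 lists not shifted the median, mean and test differed in sign, with medians between -0.01 and 0.005. Slc1a5 fell by 0.28 ± 0.057 (adjusted p = 0.00134), a call lost without the dye term (0.167). Asns (-0.13 ± 0.054), Myc (0.04), Bcl6 (-0.11), Irs2 (0.07), Ccnd1 (-0.03), Foxo1 (0.00), Foxo3 (0.03) and Foxo4 (0.09) were not called.

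**Figure D2:**
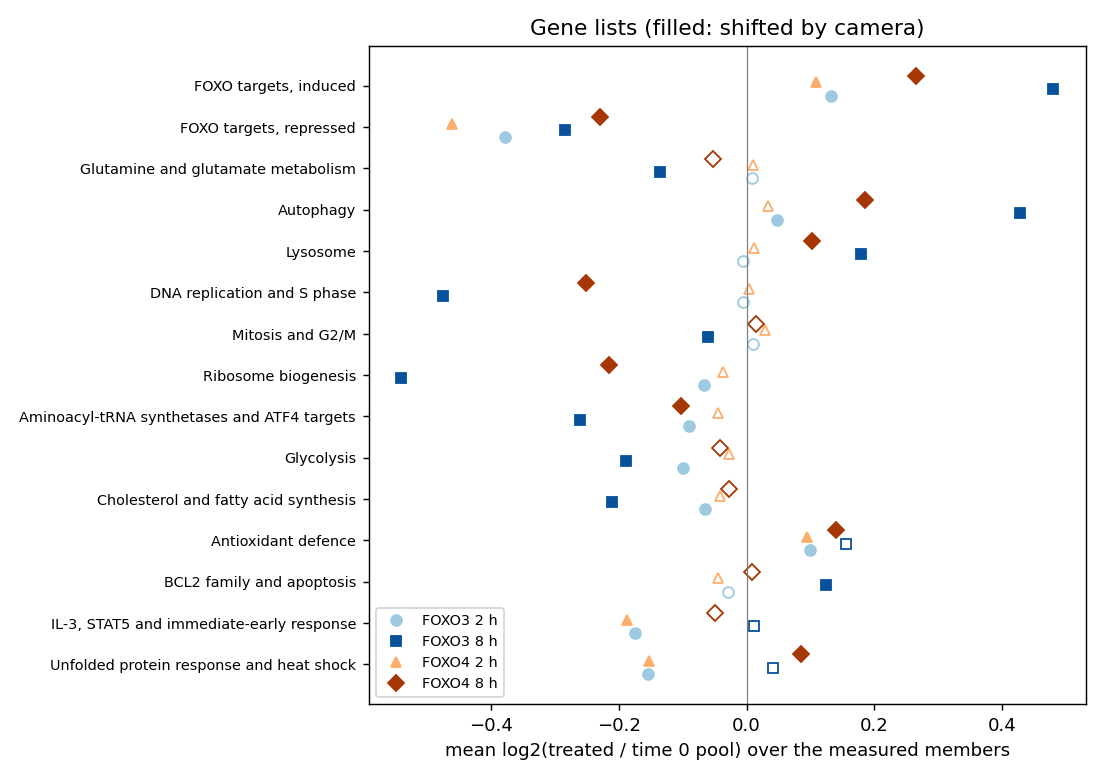
Mean log2 ratio of treated cells over the time 0 pool (x axis) of the measured members of each list that shifted in at least 1 of the 4 comparisons against 0 h (y axis). Symbols are the 4 groups, filled where camera called a shift. In FOXO3 cells at 8 h the means were -0.54 for ribosome biogenesis, -0.48 for DNA replication, 0.43 for autophagy and 0.48 for FOXO-induced genes.

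Between 2 h and 8 h in FOXO3 cells, where the pool cancels, Ube2h rose by 2.47 ± 0.096, Trp53inp1 by 2.36 ± 0.133 and Tcp11l2 by 2.18 ± 0.104, followed by Tspan8 (2.14) and Noct (2.13). Gzmb fell by 2.13 ± 0.089. Tuba8 stood at -1.66 ± 0.109, Baiap2 at -1.31, the SR splicing factor gene Srsf6 at -1.26 and Tuba4a at -1.19. At 2 h Trp53inp1 and Tcp11l2 were dim on 4 of 4 treated arrays and Ube2h on 3 of 4. The dimmer probe gave -0.02 for Noct and -0.04 for Baiap2, neither called, and 0.33 for Glul, which was called. The largest adjusted p among these 10 genes was 2.16e-09. Glul rose by 1.04 ± 0.07, Map1lc3b by 1.58 ± 0.075, Gadd45a by 1.37 ± 0.14, Bcl2l11 by 0.78 ± 0.088 and Cdkn1b by 0.37 ± 0.08, and Myc, low at 2 h, rose by 0.61 ± 0.066. In all, 3804 genes were called, 2058 higher and 1746 lower, with 2037 called without the dye term and 2233 (1065 higher and 1168 lower) with centring on the external control spots. Ccnd2 (-0.66), Slc1a5 (-0.55) and Asns (-0.44) fell, and Gabarapl1 (0.58), Ulk1 (0.54), Foxo3 (0.65) and Foxo4 (0.18) rose. Asns and Ulk1 were not called without the dye term (adjusted p = 0.0616 and 0.734), and the call of Foxo4 was lost under 5 other settings and without any of 7 single arrays of the line (adjusted p between 0.0592 and 0.115 for the arrays). Bnip3 (0.32 ± 0.121, adjusted p = 0.0769), Bcl6 (-0.01), Irs2 (0.08), Ccnd1 (0.00) and Foxo1 (-0.05) were not called.

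From 2 h to 8 h in FOXO3 cells the autophagy list shifted up, 22 genes rising, 2 falling and 19 not called (26 and 2 adjusted over the list alone; adjusted p = 1.4e-10). The list of FOXO-induced genes did so too, 19 rising, 0 falling and 25 not called (19 and 1 adjusted over the list alone; adjusted p = 4.78e-08). Leading members were Btg1 (1.17), Cdkn1a (1.03), Pik3ip1 (0.96) and Mxi1 (0.91). Ribosome biogenesis shifted down with 0 rising, 39 falling and 7 not called (2 and 42 adjusted over the list alone; adjusted p = 2.84e-24), led by Nop58 (-1.07). DNA replication shifted down with 1 rising, 33 falling and 8 not called (1 and 34 adjusted over the list alone; adjusted p = 1.32e-23), led by Uhrf1 (-1.11). Synthetases and ATF4 targets shifted down, 1 rising, 16 falling and 17 not called (2 and 16 adjusted over the list alone; adjusted p = 7.67e-05). So did cholesterol and fatty acid synthesis, 2 rising, 9 falling and 14 not called (3 and 9 adjusted over the list alone; adjusted p = 0.00486). The call of cholesterol and fatty acid synthesis was lost with the filter at the control spots (adjusted p = 0.0593), as was that of the unfolded protein response (0.0895). For 7 lists the call was lost with an estimated correlation. The lists of the interleukin-3 and STAT5 response (15 rose, 3 fell and 18 were not called; 17 and 5 adjusted over the list alone) and of the unfolded protein response (11 rose, 2 fell and 15 were not called; 12 and 3 adjusted over the list alone) shifted up, at adjusted p = 0.00117 and 0.00819. They were not shifted, at adjusted p = 0.0908 and adjusted p = 0.0632 with an estimated correlation. Ier3 (1.15), Dusp6 (1.05), Egr2 (0.91), Xbp1 (1.53), Herpud1 (0.69) and Dnajb9 (1.04) rose, and Hsp90aa1 fell by 0.68. Gzmb, a member of the interleukin-3 list, fell by 2.13.

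The other 5 of those lists in FOXO3 cells from 2 h to 8 h were lysosome (18 rose, 3 fell and 20 were not called; 20 and 3 adjusted over the list alone; adjusted p = 0.00212, and adjusted p = 0.0723 with an estimated correlation), glutamine and glutamate metabolism (4 rose, 14 fell and 12 were not called; 6 and 15 adjusted over the list alone; adjusted p = 0.00395, and adjusted p = 0.0627 with an estimated correlation) and mitosis (7 rose, 17 fell and 18 were not called; 7 and 18 adjusted over the list alone; adjusted p = 0.0187, and adjusted p = 0.0908 with an estimated correlation). Insulin, PI3K and mTOR signalling (10 rose, 2 fell and 31 were not called; 10 and 3 adjusted over the list alone) and the BCL2 family (11 rose, 3 fell and 14 were not called; 11 and 4 adjusted over the list alone) shifted up at adjusted p = 0.0441 each, and at adjusted p = 0.116 and adjusted p = 0.0853 with an estimated correlation. Atp6v1d (1.29) and the receptor gene Igf1r (1.08) rose most significantly among lysosome and signalling genes. The signalling shift was lost without FOXO3 replicate 1 (adjusted p = 0.108), 3 (0.0644) or 4 (0.058) at 2 h or 1 (0.0528), 2 (0.0529) or 3 (0.0711) at 8 h. That of the BCL2 family was lost without replicate 1 (0.0856) or 3 (0.0676) at 2 h or 3 (0.0695) or 4 (0.0543) at 8 h, and that of mitosis was lost without replicate 4 at 2 h (0.0567). With median centring the glutamine (0.0569) and mitosis (0.0885) calls were lost. With the filter at the control spots those of signalling (0.228), the BCL2 family (0.101) and mitosis (0.101) were lost. The signalling and BCL2 calls were also lost without the dye term (0.0586 each) and in a fit of the line alone (0.0527 and 0.0513). The authors' values ended the signalling call (0.0528), and the mean of probes ended the BCL2 call (0.0785). The marker lists were not shifted, at adjusted p = 0.737 for B-lineage, 0.483 for mast cell, basophil and myeloid and 0.412 for T, NK and erythroid markers. In 3 of the 13 lists not shifted the median, mean and test differed in sign.

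Between 2 h and 8 h in FOXO4 cells, Neurl3 rose by 1.64 ± 0.079, Ube2h by 1.57 ± 0.096, the annexin gene Anxa1 by 1.52 ± 0.108, Noct by 1.44 and Mgst2 by 1.41. Gzmb fell by 1.88 ± 0.089. Tuba8 stood at -1.36 ± 0.109, Baiap2 at -1.35, Srsf6 at -1.13 and the sialyltransferase gene St6gal1 at -1.04. At 2 h Neurl3, Ube2h and Mgst2 were dim on 2 of 4 treated arrays, and at 8 h St6gal1 was dim on 1 of 4. The dimmer probe gave -0.07 for Baiap2, 0.01 for Noct, 0.03 for Glul and 0.10 for Ccnd2, none called. The largest adjusted p among these 10 genes was 7.85e-07. Glul rose by 0.40 ± 0.07 (adjusted p = 0.000822), Map1lc3b by 0.78 ± 0.075, Bnip3 by 0.70 ± 0.121, Gadd45a by 0.67 ± 0.14 and Myc by 0.70 ± 0.066, and Ccnd2 fell by 0.43 ± 0.084. With the mean of a gene's probes Glul (adjusted p = 0.0634) and Ccnd2 (0.25) were not called, nor was Ccnd2 with centring on the external control spots (0.056), and without the dye term Bnip3 (0.0517) and Gadd45a (0.168) were not. Bcl2l11, at 0.31 ± 0.088 (adjusted p = 0.03), lost its call under 4 settings and without replicate 1 (0.109) or 3 (0.0969) at 2 h or replicate 1 (0.128) or 2 (0.0881) at 8 h. Asns (-0.16), Slc1a5 (-0.24), Cdkn1b (0.10), Gabarapl1 (0.11), Ulk1 (0.20), Bcl6 (-0.11), Irs2 (0.10), Ccnd1 (-0.01), Foxo1 (0.02), Foxo3 (0.01) and Foxo4 (0.16) were not called. In all, 1869 genes were called, 1179 higher and 690 lower. Without the dye term 601 were called, centring on the external control spots gave 726 higher and 114 lower, and median centring gave 1001 and 257.

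In FOXO4 cells from 2 h to 8 h the autophagy list shifted up, 12 genes rising, 0 falling and 31 not called (17 and 1 adjusted over the list alone; adjusted p = 1.56e-05). The list of FOXO-induced genes shifted up as well, 13 rising, 0 falling and 31 not called (16 and 0 adjusted over the list alone; adjusted p = 2.33e-05). Leading members were Cdkn1a (0.80) and Sod2 (0.54). The unfolded protein response and heat shock list shifted up, 13 up, 1 down and 14 not called (16 and 2 adjusted over the list alone; adjusted p = 2.46e-08), led by Xbp1 (1.13), Pdia4 (0.50) and Dnajb1 (0.67). The list of p53 targets shifted up, 6 up, 1 down and 15 not called (7 and 2 adjusted over the list alone; adjusted p = 0.00618), with Cdkn1a and Trp53inp1 (1.29) higher. DNA replication shifted down, 0 rising, 20 falling and 22 not called (0 and 26 adjusted over the list alone; adjusted p = 3.62e-18), led by Tk1 (-0.73). Ribosome biogenesis shifted down, 0 rising, 15 falling and 31 not called (0 and 17 adjusted over the list alone; adjusted p = 4.11e-10), led by Ddx21 (-0.55). The lysosome list (10 rose, 1 fell and 30 were not called; 10 and 3 adjusted over the list alone; adjusted p = 0.0104, but adjusted p = 0.157 with an estimated correlation) and the interleukin-3 and STAT5 list (11 rose, 3 fell and 22 were not called; 13 and 3 adjusted over the list alone; adjusted p = 0.00067, but adjusted p = 0.133 with an estimated correlation) shifted up. With the filter at the control spots the calls of the p53 list (adjusted p = 0.0533) and the lysosome list (0.0545) were lost. In the interleukin-3 list Ier3 (1.11), Dusp5 (1.01) and Id1 (0.93) rose, while Gzmb, also a member, fell. The marker lists were not shifted, at adjusted p = 0.517 for B-lineage, 0.207 for mast cell, basophil and myeloid and 0.544 for T, NK and erythroid markers. In 3 of the 18 lists not shifted the median, mean and test differed in sign.

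At 2 h the responses of the lines differed in 6 genes, 3 higher and 3 lower in FOXO3 cells, and 961 genes had an unadjusted p under 0.05. Between the lines, higher and lower refer to the ratio over each line's own pool and not to the transcript level. Gata2 fell by 0.47 ± 0.051 in FOXO3 and by 1.06 ± 0.051 in FOXO4 cells, a difference of 0.59 ± 0.072 (adjusted p = 0.0018), and the transferrin receptor gene Tfrc (0.44 ± 0.069) and Gfi1b (0.36 ± 0.056) also fell less in FOXO3 cells. The stress gene Ddit4 differed by -0.65 ± 0.063 (adjusted p = 0.000111), Atf4 by -0.41 ± 0.064 and Herpud1 by -0.34 ± 0.057. Ddit4 was dim in treated cells on 2 of 4 arrays of each line, Herpud1 on 3 of 4 of FOXO3 and 2 of 4 of FOXO4, and Gfi1b on 2 of 4 of FOXO3. Under centring on the external control spots Ddit4 (adjusted p = 0.341), Tfrc (0.523), Gfi1b (0.715), Atf4 (0.916) and Herpud1 (0.916) were not called. The last 4 were not called without the dye term (0.199, 0.204, 0.199 and 0.216), with median centring (0.187, 1, 0.2 and 0.517) or with offset 16 (0.0659, 0.3, 0.0847 and 0.0659) either. Without FOXO4 replicate 1 at 2 h 2 genes were called in all. Leaving out FOXO3 replicate 3 or 4 or FOXO4 replicate 1 or 2 at 2 h ended the call of Tfrc (adjusted p of at most 0.118). That of Gfi1b ended without FOXO3 replicate 1 or 4 or any FOXO4 replicate of 2 h (at most 0.101). That of Atf4 ended without FOXO3 replicate 2, 3 or 4 or FOXO4 replicate 1, 2 or 3 of 2 h (at most 0.136). That of Herpud1 ended without any of the 8 arrays of 2 h (at most 0.154), and it also ended without 5 single arrays of 8 h (0.0502 to 0.057). Glul (0.21 ± 0.07), Gadd45a (-0.31 ± 0.14), Map1lc3b (0.06), Bcl2l11 (0.03), Cdkn1b (-0.02), Gabarapl1 (-0.08), Bnip3 (-0.12), Ulk1 (-0.13), Asns (-0.06), Slc1a5 (-0.03), Myc (-0.04), Bcl6 (0.01), Irs2 (0.01), Ccnd1 (0.00), Ccnd2 (0.02), Foxo1 (0.05), Foxo3 (0.03) and Foxo4 (0.05) were not called. Of the lists, glycolysis was lower in FOXO3 cells (0 genes higher, 0 lower and 24 not called; 0 and 2 adjusted over the list alone; adjusted p = 0.012, but adjusted p = 0.507 with an estimated correlation and 0.413 with fry). Hk2 stood at -0.32 and Slc2a1 at -0.26. That shift was lost without FOXO3 replicate 3 (adjusted p = 0.372) or FOXO4 replicate 1 (0.081) or 2 (0.149) at 2 h. The marker lists stood at adjusted p = 0.311, 0.955 and 0.311, and in 5 of the 25 lists not shifted the median, mean and test differed in sign.

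At 8 h the responses differed in 1862 genes, 939 higher and 923 lower in FOXO3 cells, and 16 were higher and 0 lower by at least 1 on the log2 scale. The alpha-globin genes Hba-a2 and Hba-a1, which are near-identical, were higher by 1.43 ± 0.08 and 1.42 ± 0.081, Ypel3 by 1.38 ± 0.06, the receptor gene Erbb3 by 1.30 ± 0.084 and Ccpg1 by 1.25 ± 0.079. The difference was -0.90 ± 0.063 for Hk2, -0.83 ± 0.067 for Cdca7 and -0.75 ± 0.099 for Pbp2. It was -0.69 for Dut, which encodes dUTPase, and for Cnpy4. Hk2 stood at -0.96 in FOXO3 and -0.07 in FOXO4 cells, and Hba-a1 rose by 1.76 in FOXO3 and by 0.34 in FOXO4 cells. Glul was higher in FOXO3 cells by 0.85 ± 0.07 (adjusted p = 3.4e-07) and Map1lc3b by 0.86 ± 0.075 (adjusted p = 7.08e-07). The dimmer probe of Glul gave 0.26 and was not called. The largest adjusted p among the 10 genes first named was 5.41e-05. At time 0 Erbb3, Ypel3, Ccpg1 and Hba-a2 were dim on at least 1 array, and the other probe gave 0.06 for Ccpg1 while 1 of 2 other probes of Erbb3 was called. The count was 557 without the dye term and 612 with centring on the external control spots, and median centring gave 545 higher and 932 lower.

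The ratios over each line's own pool at 8 h were higher in FOXO3 than in FOXO4 cells for Bcl2l11 (0.50 ± 0.088), Gabarapl1 (0.40 ± 0.061) and Foxo3 (0.67 ± 0.063). They were lower for Bnip3 (-0.50 ± 0.121), Asns (-0.34 ± 0.076) and Slc1a5 (-0.35 ± 0.08). Without the dye term Bnip3 (adjusted p = 0.227), Asns (0.35) and Slc1a5 (0.397) were not called, nor were Gabarapl1 (0.0933) and Asns (0.117) with centring on the external control spots. Cdkn1b (0.25, adjusted p = 0.0517), Gadd45a (0.38), Ulk1 (0.21), Ccnd2 (-0.20), Myc (-0.13), Bcl6 (0.11), Irs2 (-0.02), Ccnd1 (0.02), Foxo1 (-0.02) and Foxo4 (0.07) were not called. The autophagy list was higher in FOXO3 cells, 17 genes higher, 1 lower and 25 not called (20 and 1 adjusted over the list alone; adjusted p = 2.45e-11). So was the list of FOXO-induced genes, 12 higher, 0 lower and 32 not called (16 and 1 adjusted over the list alone; adjusted p = 1.81e-07), led by Txnip (0.94) and Btg1 (1.09). The BCL2 family shifted the same way, 8 higher, 1 lower and 19 not called (8 and 3 adjusted over the list alone; adjusted p = 0.00565), with Mcl1 (0.41) and Casp6 (0.51).

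Lower in FOXO3 than in FOXO4 cells at 8 h were ribosome biogenesis (0 higher, 36 lower and 10 not called; 0 and 38 adjusted over the list alone; adjusted p = 2.17e-29) and DNA replication (1, 18 and 23; 1 and 25 adjusted over the list alone; adjusted p = 8.17e-16). Also lower were synthetases and ATF4 targets (0, 11 and 23; 0 and 15 adjusted over the list alone; adjusted p = 1.09e-07), cholesterol and fatty acid synthesis (0, 8 and 17; 0 and 9 adjusted over the list alone; adjusted p = 2.84e-07) and mitosis (3, 11 and 28; 4 and 14 adjusted over the list alone; adjusted p = 0.00134). Nop58 (-0.67), Rrm2 (-0.67), Eprs (-0.33), Scd2 (-0.69) and Ccna2 (-0.50) were among their lower genes. The list of glutamine and glutamate metabolism was lower too (2 higher, 11 lower and 17 not called; 3 and 11 adjusted over the list alone; adjusted p = 0.0017), with Glul and Ctps2 (0.64) the genes that were higher. Amino acid transporters (1 higher, 3 lower and 18 not called; 2 and 7 adjusted over the list alone; adjusted p = 0.0419, but adjusted p = 0.0851 with an estimated correlation), with Slc38a1 (-0.39) and Slc7a5 (-0.36), and glycolysis (0 higher, 5 lower and 19 not called; 1 and 7 adjusted over the list alone; adjusted p = 0.00134, but adjusted p = 0.098 with an estimated correlation), with Hk2 and Pdk1 (-0.46), were lower at the preset correlation. The transporter shift was lost without FOXO3 replicate 2 (adjusted p = 0.0968) or 3 (0.0538) or FOXO4 replicate 1 (0.0559), 2 (0.0511) or 3 (0.0678) at 8 h, and with the filter at the control spots (0.0582), no background subtraction (0.0507), no dye term (0.0634) or offset 16 (0.0571). Oestrogen receptor targets (adjusted p = 0.125), interferon response genes (0.532), the TCA cycle and respiratory chain (0.894) and G1 cyclins and CDKs (0.268) were not shifted here or in any of the other comparisons, nor were the marker lists of B-lineage cells (0.489), mast cells, basophils and myeloid cells (0.908) and T, NK and erythroid cells (0.24). In 2 of the 15 lists not shifted the median, mean and test differed in sign. These list shifts too are differences in the ratio over each line's own pool. Each construct was studied in 1 line, so line and construct cannot be told apart.

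**Figure D3:**
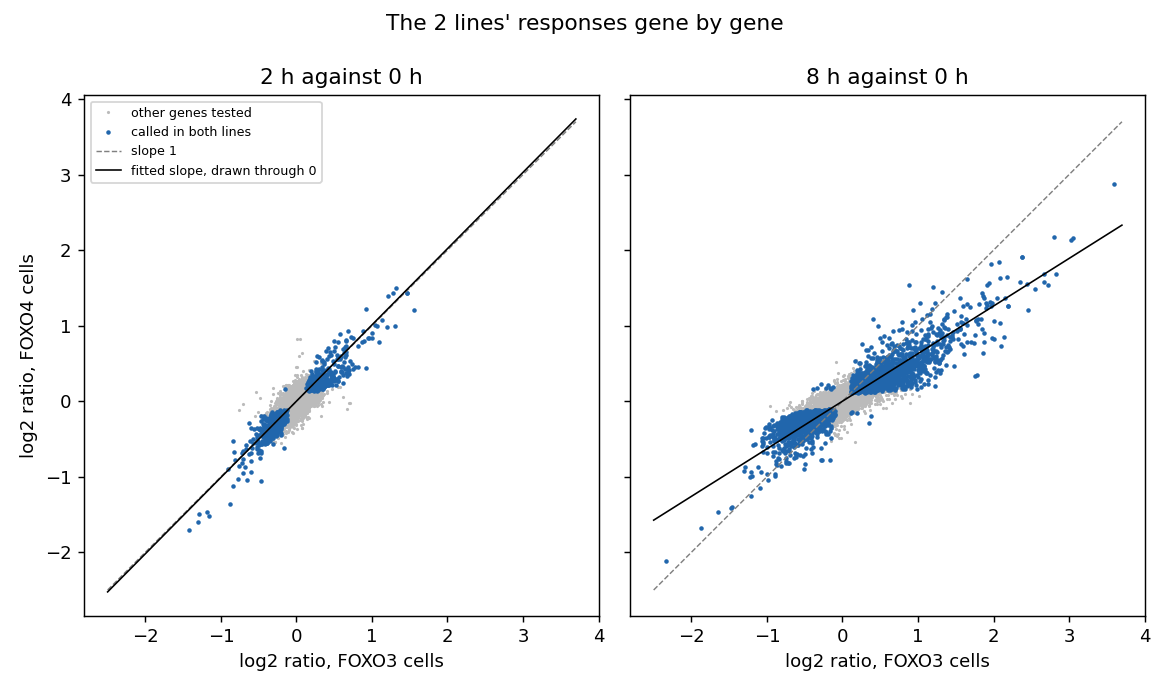
Log2 ratios over the time 0 pool in FOXO3 cells (x axis) and FOXO4 cells (y axis) at 2 h (left) and 8 h (right), 1 point per gene, blue where called in both lines. The dashed line has slope 1 and the solid line the slope fitted over the blue points, 1.01 at 2 h and 0.63 at 8 h.

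At 2 h, of 1364 genes called in FOXO3 and 1538 in FOXO4 cells, 868 were called in the same direction in both lines (343 higher and 525 lower, where independent lists would share 20.5 and 41.0) and 1 in opposite directions, and across genes the ratios correlated with r = 0.74 and rho = 0.47. At 8 h, of 5329 and 3227 genes, 2886 were shared (1527 higher and 1359 lower, where independent lists would share 260.9 and 231.1) and 13 were opposite, with r = 0.87 and rho = 0.68. Noct, Cited2, Klf6, Gzmb, Tuba8 and Banp were among the genes named for both lines. The lines had different pools, and genes are not independent replicates. Both lines were given 4-OHT, so changes they share cannot be told apart from effects of 4-OHT itself, time in culture or handling. Without the dye term 293 genes were shared at 2 h, of 466 and 480 called, and 1484 at 8 h, of 3392 and 1608. With centring on the external control spots 403 were shared at 2 h, of 529 and 1204, and 1726 at 8 h, of 4086 and 1856.

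Within a line, 907 genes were called in the same direction at 2 h and 8 h in FOXO3 cells (437 higher and 470 lower, where independent lists would share 93.2 and 114.5) and 140 in opposite directions, with r = 0.47, rho = 0.26 and a covariance of 0.0161 across genes. Srsf6 rose by 0.55 at 2 h and fell by 0.71 at 8 h. In FOXO4 cells 790 were shared (346 and 444, against 57.5 and 82.8) and 132 were opposite, with r = 0.46, rho = 0.27 and a covariance of 0.0104. Both times were set against the same pool: unchanged groups against a pool that deviated as 1 array does would share 2300 and 2340 genes, with r = 0.80 and covariances of 0.0121 and 0.0122. The lines had separate pools, and between FOXO3 at 2 h and FOXO4 at 8 h 727 genes were shared (374 and 353, against 58.8 and 66.3) and 104 were opposite, with r = 0.47. Between FOXO4 at 2 h and FOXO3 at 8 h 871 were shared (363 and 508, against 91.0 and 142.9) and 251 were opposite, with r = 0.36. These overlaps, which were counted after the others were seen, rest on no shared pool. At 727 and 871 genes they were near the 907 and 790 within a line, so overlap of that size arose without one. The lines differed in 6 genes at 2 h, which argues against separate pool errors as large as those simulated. How much of the overlap within a line came from the pool was not measured. Without the dye term the overlaps between lines and times were 265 and 324, and the first was 283 with centring on the external control spots. Fewer genes were shared within a line as well under these 2 settings.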

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

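Of the tests in this part, those of ratio compression, of 1 common factor as the whole cause, of clones and of admixed erythroid cells and the dye term for each line were chosen only after the result was seen.

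The lines differed in 6 genes at 2 h and in 1862 at 8 h by the test of the difference itself. At 2 h the differences, FOXO3 minus FOXO4, were 0.59 for Gata2, 0.44 for Tfrc, 0.36 for Gfi1b, -0.65 for Ddit4, -0.41 for Atf4 and -0.34 for Herpud1. At 8 h the largest were 1.43 for Hba-a2, 1.42 for Hba-a1, 1.38 for Ypel3, 1.30 for Erbb3 and 1.25 for Ccpg1. In the other direction they were -0.90 for Hk2, -0.83 for Cdca7, -0.75 for Pbp2, -0.69 for Dut and -0.69 for Cnpy4.

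In 8 of 152 groups of 4 arrays examined, 1 array lay far from the other 3 after the dye term was removed, 5 of the 8 in FOXO3 cells at 8 h. Chance picks about 1 in 20 groups. In FOXO3 cells at 8 h, replicate 3 was at 3.09 for Trp53inp1 (others 2.72 to 2.74), 0.69 for Cdkn1b (0.45 to 0.46) and -0.03 for Myc (-0.13 to -0.12). There replicate 1 was at 0.48 for Foxo3 (0.74 to 0.78) and 0.04 for Ccnd1 (-0.04 to -0.03). Foxo1 was at -0.05 in FOXO3 replicate 1 at 2 h (0.05 to 0.06). Ier3 was at -0.97 in FOXO4 replicate 2 at 2 h (-1.19 to -1.16) and Glul at 0.46 in FOXO4 replicate 2 at 8 h (0.35 to 0.36).

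The response at 8 h was larger in FOXO3 than in FOXO4 cells, with a slope of FOXO4 on FOXO3 ratios of 0.63 over the genes called in both lines (0.62 to 0.66 leaving out 1 array). Compression of ratios on the arrays of the FOXO4 line would lower the slope at both times, but at 2 h it was 1.01 (0.97 to 1.05), which argues against it. After scaling by 1 common factor 36.25% of the 1862 differences (675 genes) were still called, and 948 genes were called in all. The scaling widened the spread of the FOXO4 arrays of 8 h alone, while the test used 1 spread shared by all groups. These counts may therefore be too high. The factor of 0.6, the best of those tried from 0.3 to 1, left 425 genes called (at least 224 leaving out 1 array), which argues against 1 common factor as the whole cause, while its part in the other differences cannot be told apart from gene-specific ones. A difference between clones or in the level of the fusion protein stays open, since there was 1 line per construct.

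The alpha-globin probes rose in FOXO3 cells at 8 h (Hba-a1 by 1.76). Enough admixed erythroid cells would raise other erythroid transcripts as well, but the median of 16 other erythroid genes was 0.01 ± 0.05. This SE came from resampling the 16 genes, which are not replicates, and leaves out the spread between arrays. The median argues against an admixture large enough to move these genes as a set. It cannot exclude a trace seen in alpha-globin alone. Of the 16 genes, 3 rose (Fech by 0.39, Tfrc by 0.23 and Car2 by 0.18) and 4 fell, among them Klf1 (-0.81) and Gata1 (-0.15). Hbb-b2 was at 0.11 and was not called. Klf1 and Gata1 were lower at 2 h in both lines too, so their fall says little about admixed cells. Hba-a1 and Hba-a2 are near-identical, so their probes may read each other's transcripts, and a difference between the lines stays open as untested.

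For the counts of genes, the arrays of the 2 groups compared were split in every other way. For 8 h against 2 h the real split called the most genes in FOXO3 cells (3804 against 341 in the highest other) and in FOXO4 cells (1869 against 673). Both of those other splits followed the dye orientation. The same held for the lines at 8 h (1862 against 1). In each case 1 of 35 splits was as large, the real one itself, which is the smallest share this check can give. The other splits mix the 2 groups, which raises the spread and lowers their counts, so the check cannot exclude chance by itself. Nor does it test what is fixed to a line, such as clone or pool. For the lines at 2 h, 2 of 35 splits gave at least the 6 genes, and chance cannot be excluded there either. The highest other split there gave 502, and it set the dye orientations crosswise against the lines, which points to a structure of dye by line. With a dye term for each line 8 genes were called.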

How the results depend on the processing

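The filter at the control spots, the dye term for each line and the overlaps between lines and times were chosen only after the result was seen. Of 8480 values of named genes under other settings, 8332 kept their side of the threshold, 107 were no longer called and 41 became called. Many of these genes were named for the highest or lowest ratios of the main fit, so their retention was largely fixed in advance. Some settings left out an array of a group outside the comparison, which kept the compared arrays as they were. The retention therefore does not describe called genes in general, whose counts are given below. Among values called in the main fit or under the other setting, 0 were reversed. Changes of sign among values called in neither were not counted. Of 2403 values of shifted lists 2296 were kept and 107 were no longer called. Where counts moved, the cause was not tested.

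Genes called without the dye term were 466 and 3392 (FOXO3 at 2 h and 8 h), 480 and 1608 (FOXO4), 2037 and 601 (8 h against 2 h in FOXO3 and FOXO4) and 2 and 557 (lines at 2 h and 8 h). Shared genes were 293 and 1484 between lines, 340 and 277 between times and 265 and 324 between lines and times (FOXO3 and FOXO4 at 2 h). Centring on the external control spots called 529 (FOXO3 at 2 h), 1856 (FOXO4 at 8 h), 2233 and 840 (8 h against 2 h) and 1 and 612 (lines), with 403 and 1726 shared between lines, 385 and 457 between times and 283 between FOXO3 at 2 h and FOXO4 at 8 h. Median centring called 1009 for FOXO4 at 2 h with 501 shared between times, and 2 for the lines at 2 h, where normexp with offset 16 gave 2 and the authors' values 10. Lists shifted with an estimated correlation were 6 for FOXO3 at 8 h and from 2 h to 8 h, 4 for FOXO4 at 8 h and 0 for the lines at 2 h (1 at an unadjusted p under 0.05). With fry they were 19, 23, 17 and 17 against 0 h, 22 and 16 for 8 h against 2 h and 0 for the lines at 2 h (2 unadjusted), where camera at the preset correlation gave 1 (3 unadjusted). The filter at the control spots left 8 lists for FOXO3 from 2 h to 8 h. For the lines at 2 h the external controls, the probe mean and the authors' values gave 2 each and median centring 4.

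Centring moved the balance of higher against lower calls. On the external control spots it was 1534 to 2552 for FOXO3 at 8 h (2688 to 2641 with loess alone), 110 to 1094 for FOXO4 at 2 h (592 to 946), 823 to 1033 for FOXO4 at 8 h, 1065 to 1168 for FOXO3 from 2 h to 8 h (2058 to 1746), 726 to 114 for FOXO4 from 2 h to 8 h (1179 to 690) and 1 to 0 for the lines at 2 h (3 to 3). With median centring it was 2249 to 2653 for FOXO3 at 8 h, 1663 to 968 for FOXO4 at 8 h (1697 to 1530), 1001 to 257 for FOXO4 from 2 h to 8 h and 545 to 932 for the lines at 8 h (939 to 923).

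Leaving out 1 array gave 2 to 6 genes and 0 to 3 lists for the lines at 2 h and 1015 to 1581 genes for FOXO4 at 2 h. The 1015 came without FOXO4 replicate 1 of 2 h, the 2 genes without FOXO4 replicate 1 or 2, and the 0 lists without FOXO3 replicate 3 or FOXO4 replicate 2. The other ranges were 948 to 1504, 4738 to 5473 and 2529 to 3388 for FOXO3 at 2 h and 8 h and FOXO4 at 8 h. They were 3414 to 3954 and 1442 to 1894 for 8 h against 2 h, and 1429 to 1995 for the lines at 8 h.

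Replicate numbers did not pair the arrays, as own-number correlations ran from -0.39 to 0.17 and 2 of 8 were best with their own number. With the replicate block 1308, 5342, 1403 and 3123 genes were called against 0 h, 3772 and 1726 for 8 h against 2 h and 3 and 1752 for the lines. The low signal limits what can be seen, since only 30.4% to 42.4% of probes exceeded the control spots. Arrays of opposite dye correlated as low as -0.593 within a group before the dye term.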

Other observations

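The lists in this part and the test of lasting FOXO activity and that of 4-OHT and handling were chosen only after the result was seen.

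The SR splicing factor genes Srsf2, Srsf5 and Srsf6 rose at 2 h and fell at 8 h in both lines. Of 16 SR splicing factor and CLK kinase genes, 4 rose and 1 fell in FOXO3 cells at 2 h and 3 rose and 10 fell at 8 h. In FOXO4 cells 5 rose and 1 fell at 2 h and 3 rose and 6 fell at 8 h. The other genes that rose at 2 h were Clk1 in both lines and Clk4 in FOXO4 cells, and they did not fall at 8 h. In FOXO3 cells Srsf3 (-0.40), Srsf4 (-0.53) and Srsf7 (-0.52) fell at 8 h without a call at 2 h, so the counts alone do not show a reversal. The surplus of falling genes in FOXO4 cells at 8 h was gone with median centring (3 rose and 3 fell), and 1 rose and 4 fell with centring on the external control spots. Srsf5 stood at 0.65 and -0.32 in FOXO3 cells and at 0.59 and -0.39 in FOXO4 cells at 2 h and 8 h. In the same order Srsf6 stood at 0.55 and -0.71 and at 0.47 and -0.66, and Srsf2 at 0.19 and -0.56 and at 0.40 and -0.26. Clk1, which encodes a kinase of these factors, was higher throughout, at 1.56 and 1.80 in FOXO3 and 1.21 and 1.03 in FOXO4 cells. Srsf11 was lower, at -0.43, -0.21, -0.32 and -0.14. These genes kept their signs under 4 other scalings, but Srsf2 at 2 h in FOXO3 cells was not called with centring on the external control spots (adjusted p = 0.493) or median centring (0.296), nor was Srsf11 at 8 h in FOXO4 cells (0.157 and 0.564).

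At 2 h Cirbp, a cold-inducible gene, stood at 1.13 in FOXO3 and 1.07 in FOXO4 cells (0.23 and 0.20 at 8 h), and of 18 heat shock factor targets, not tested as a list, 0 rose and 7 fell in FOXO3 and 1 rose and 7 fell in FOXO4 cells, with medians of -0.11 and -0.12. At 8 h 1 rose and 11 fell in FOXO3 cells (median -0.30) and 1 rose and 4 fell in FOXO4 cells (-0.07). With median centring 1 rose and 2 fell in FOXO4 cells at 8 h, with a median of -0.01. With centring on the external control spots 0 rose and 4 fell in FOXO3 cells at 2 h. The gene that rose in FOXO4 cells at 2 h, Hspb1, was not called under 3 of 4 other scalings. A drop in temperature at treatment or harvest may have taken part: the other cold-inducible gene, Rbm3, was higher too, by 0.30 in FOXO3 and 0.28 ± 0.07 in FOXO4 cells, as that explanation needs. Rbm3 was also higher at 8 h (0.23 and 0.26), but with centring on the external control spots it lost its calls at 2 h (0.28 and 0.18, adjusted p = 0.151 and 0.28) and 8 h (0.16 and 0.22, adjusted p = 0.282 and 0.172), as Cirbp did at 8 h (0.182 and 0.354), and with median centring those at 2 h (0.25 and 0.23, adjusted p = 0.186 and 0.224) and that at 8 h in FOXO3 cells (0.0763). FOXO activity that lasts to 8 h cannot be told apart from a drop in temperature. The median of the 8 h minus the 2 h ratio of the targets was -0.12 ± 0.092 in FOXO3 and -0.02 in FOXO4 cells. That SE came from resampling the targets, which are not replicates. Nor can 4-OHT itself or the handling of the cultures be told apart, since 0 arrays of cells without a fusion protein were analysed here.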
